A study of Mus musculus with 16 samples.

How the data were processed

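RNA from glomerular extracts of kidney cortex of 16 female mice was hybridised to 16 Affymetrix arrays, 1 per mouse, after amplification of 10 ng of RNA with a Pico kit, per the labels. Mice were C57Bl/6 wild type or ERα knockout on that background, untreated or taken 18 hours, 6 days or 2 weeks after nephrotoxic serum at 8 ul per g, with 2 mice in each of the 8 groups. The deposited table holds log2 values for 72688 probesets, summarised and normalized between arrays by the authors before deposit. Per the submitters' processing notes, Affymetrix Expression Console and Transcriptome Analysis Console were used. Their versions, the summarisation method and the annotation build are not given in the sources used here. The array medians lay between 5.57 and 5.9 and the values between 2.22 and 19.93. Because 152 genes (0.504%) had a mean above the log2 of the largest 16-bit scanner value, a transformation beyond a plain log2 of scanner signal is present and unstated, so differences are given in deposited log2 units. The alternative of log2 of the value plus 16, planned for a table not in log2, was not applicable. No probe's level was set against another probe's.

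Probesets with exactly 1 gene symbol (30604) were used. Those with several symbols (2146) and with none (39938) were left out of the gene tests, and every column of values was used. Symbols of 827 probesets were updated through the Entrez identifier, and 30294 of the single-symbol probesets were found in the gene reference. Where a gene had more than 1 probeset (355 genes), that with the highest mean over all 16 arrays was taken, which left 30142 genes. No filter on brightness was applied. Groups were taken from the labels, and no array was moved to another group.

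Each gene was fitted in limma 3.58.1 (R 4.3.3) with a mean for each of the 8 groups over all 16 arrays, which leaves 8 residual degrees of freedom, and variances were moderated with an intensity trend (prior degrees of freedom 3.03). Contrasts were knockout minus wild type averaged over the 4 times and at each time, each time after serum minus untreated within each genotype, the difference of those responses between genotypes at each time, and an F test over the 3 differences. The p-values were adjusted by Benjamini-Hochberg over all genes within a contrast, and a gene was called at an adjusted p under 0.05. Standard errors come from the moderated variance. Standard deviations are between arrays.

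Gene lists were fixed before the data were examined, 30 in all, and 29 had at least 5 measured members. The erythroid list had 2 measured and was not tested. Some genes stand in more than 1 list, such as Scd1 and Cyp4a14. Each list was tested with camera at a preset inter-gene correlation of 0.01 against all other genes, with Benjamini-Hochberg over the lists within a contrast, and again with an estimated correlation and with fry, whose direction p asks whether a list moves, on balance, one way. Counts of list members that pass are given over all genes tested and adjusted over the list alone.

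Genes were named by a rule fixed before the data were examined: Esr1, the 10 largest rises and 6 largest falls among called genes (for the genotype average 10 and 10, with the same sign at all 4 times), all where fewer were called, or the 3 smallest p-values, said not to pass, where none was. Symbols of numbered predicted transcripts, pseudogenes, small RNAs, odorant and vomeronasal receptors and antigen receptor segments were counted and not named. Up to 4 members per list with the largest absolute change complete the rule. For the added settings some of the named genes are shown, and Xist was chosen after its values were seen.

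The procedure was tested on simulated data, in which 67, 67 and 66 genes were changed by 1, 2 and 4 log2 units over random noise with each gene's own residual spread. For the genotype average over 16 arrays it recovered 92.5%, 97% and 100% of them, with 5 false calls, and over 14 arrays 86.6%, 95.5% and 100%, with 13. For wild type at 2 weeks it recovered 52.2%, 91% and 98.5%, with 7 false calls, and for the difference of responses at 2 weeks 35.8%, 77.6% and 92.4%, with 7. The changed list was called each time, and 1 unchanged list was called falsely for wild type at 2 weeks. The simulated noise was independent between genes and between arrays, and no simulated array carried the pattern of another group. The recovered shares and list calls therefore do not show how the procedure does with correlated genes or discordant arrays.

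Alternatives fixed beforehand left out dim genes, averaged probesets, tested all probesets, used quantile normalization or median centring, changed the variance moderation, weighted arrays, fitted only the groups compared, added a term for replicate number, added a tubule covariate (proximal tubule minus podocyte marker mean), or left out each array in turn. Alternatives added after the data were seen left out both 18-hour replicate 2 arrays, these and knockout 2 weeks replicate 1, or all 18-hour arrays. Where a group is left with 1 array, planned or added, it is assumed to vary like the others. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.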

Results

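RNA was measured on 1 array for each of 16 female mice, from extracts of glomeruli, the filtering units of the kidney. Of these mice, 8 were wild type (C57Bl/6) and 8 lacked oestrogen receptor alpha (knockout), the receptor encoded by Esr1. In each genotype 2 mice were untreated and 2 each were taken 18 hours, 6 days and 2 weeks after sheep nephrotoxic serum, an antiserum that binds the glomerular basement membrane and starts glomerulonephritis. The series asks how the receptor bears on lipid metabolism and on this disease. The deposited log2 values ran from 2.22 to 19.93, and the array medians from 5.57 to 5.9. Because 152 genes had a mean above the log2 of the largest value a 16-bit scanner can give, the values carry a transformation that is not stated. Differences are therefore given in deposited log2 units, not as folds of RNA. Precision is limited by the 2 arrays per group. In the fit of all 16 arrays a p-value sets a difference against a spread between replicates shared by all 8 groups. That spread is not the one of the groups compared alone.

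Esr1, the gene the knockout mice are named for, was not lower in the knockout arrays. It stood at 6.90 ± 0.35 in wild type and 7.44 ± 0.18 in knockout (SD, n = 8 each), a difference of 0.55 ± 0.11 (SE; limma adjusted p = 0.218). Leaving out 1 array gave adjusted p from 0.0324 to 0.525, with a call without knockout 2 weeks replicate 2 (0.54) or wild type 18 hours replicate 2 (0.63). The part of Esr1 that the probeset covers and the part deleted are not given in the sources used here. Whether its signal checks the deletion therefore cannot be told. At 18 hours Esr1 was 6.85 and 7.53 in wild type replicates 1 and 2, and 7.64 and 7.11 in knockout replicates 1 and 2. Xist, expressed from the inactive X chromosome of females, was between 16.47 and 17.38 in every array.

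Genes with higher levels in male kidney split the arrays, and 2 arrays sat with the other genotype. Abcc3, an exporter of organic anions, stood at 12.57 ± 0.39 in untreated wild type and 5.95 ± 0.04 in untreated knockout (SD, n = 2). At 18 hours it was 13.09 and 6.25 in wild type replicates 1 and 2, and 6.50 and 12.93 in knockout replicates 1 and 2. The mean of 15 genes with higher levels in male kidney was 10.40 and 15.31 in those wild type arrays and 14.48 and 10.09 in those knockout arrays. The mean of 5 female-biased genes was 15.82 and 13.08, and 12.94 and 15.36, in the same arrays. It did not split all arrays by genotype. In wild type at 2 weeks it was 11.80 and 13.00, near the 11.95 and 12.64 of untreated knockout. A 3rd array stood apart in another way: knockout 2 weeks replicate 1 had Havcr1, a tubule injury marker, at 7.17 and its replicate had it at 12.77. Its proximal tubule marker mean was 15.26 against 13.46 in replicate 2, and 556 genes differed by more than 2 log2 units between these replicates. Labels were kept as given throughout. Counts without the doubtful arrays are named as the 14 arrays (without both 18-hour replicates 2), the 13 arrays (also without knockout 2 weeks replicate 1) and the 12 arrays (without any 18-hour array), all chosen after the data were seen.

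**Figure D1:**
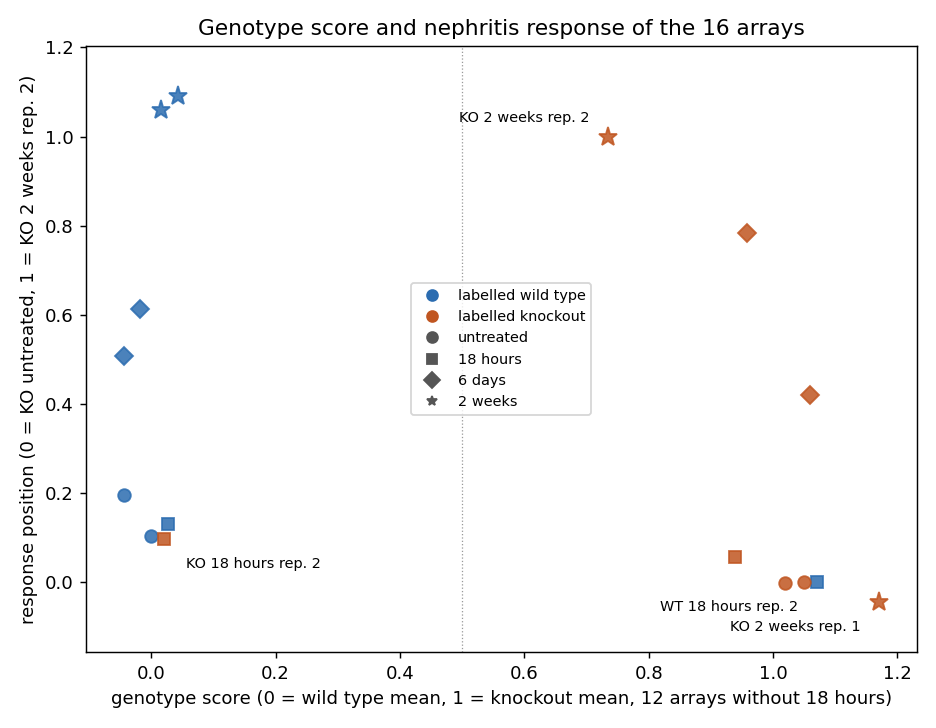
Each of the 16 arrays is placed by its genotype score over 449 genes (horizontal, 0 at the wild type mean and 1 at the knockout mean of the 12 arrays without 18 hours) and its position over 388 serum response genes (vertical, 0 at untreated knockout and 1 at knockout 2 weeks replicate 2), with colour for the labelled genotype and shape for the time. The wild type and knockout replicates 2 at 18 hours lie at scores of 1.07 and 0.0203, and knockout 2 weeks replicate 1 lies at a response position of -0.0433. The 449 genes were called over the 12 arrays, so only the 18-hour scores are held out. The 388 genes were called higher at 2 weeks in both genotypes without knockout 2 weeks replicate 1. The other 2-week arrays lie high by that choice.

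The first comparison asks which transcripts differed between knockout and wild type averaged over the 4 times. Male-biased kidney genes lay higher and female-biased genes lower in knockout, but over all 16 arrays no gene passed. Neither list held with an estimated correlation (adjusted p = 0.297 for both). Limma called 0 of 30142 genes, with 3514 at an unadjusted p under 0.05. The smallest p-values belonged to Lgals12, an adipocyte galectin (-0.70 ± 0.09, adjusted p = 0.103), and to the complement component 4 genes. These were C4b (1.36 ± 0.17, adjusted p = 0.103) and C4a (0.72 ± 0.10, adjusted p = 0.128). Over the 14 arrays 519 genes were called, 217 higher and 302 lower in knockout. Over the 12 arrays 449 were called, 389 of them among the 519. Leaving out 1 array gave 2196 genes without knockout 2 weeks replicate 2, 46 without wild type 18 hours replicate 2, 40 without wild type 2 weeks replicate 1 and 2 without knockout 18 hours replicate 2. The 14 and the 12 arrays were chosen by their values, which favours calls, so their counts are not on the footing of the 16-array count. Leaving out each array in turn was fixed beforehand. Without knockout 2 weeks replicate 2, knockout at 2 weeks was replicate 1 alone. Replicate 1 had a response position of -0.0433, against 1.06 and 1.09 in wild type at 2 weeks. The 388 genes behind this position were called higher at 2 weeks in wild type and in knockout without replicate 1. High wild type values follow from that choice, while replicate 1 was held out of it. The count without replicate 2 therefore mixes a lack of response with genotype.

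Among the 519 genes, the amino acid transporter Slc7a13 was higher in knockout by 9.31 ± 0.92 (adjusted p = 0.0016) and the organic anion uptake carrier Slco1a1 by 6.40 ± 0.93 (adjusted p = 0.0128). The glucuronosyltransferases Ugt2b37 and Ugt2b5 were higher by 7.38 ± 0.55 and 4.99 ± 0.49 (adjusted p = 0.000388 and 0.00152). Among cytochrome P450 genes, Cyp2j13 was higher by 7.37 ± 0.40 (adjusted p = 6.03e-05), and Cyp2e1 by 5.77 ± 0.47 (adjusted p = 0.000631). Cyp4a12a and Cyp4a12b, which hydroxylate arachidonic acid, were higher by 5.63 ± 0.96 and 4.90 ± 0.85 (adjusted p = 0.0242 and 0.0262). Acsm3, a medium-chain acyl-CoA synthetase, was higher by 6.79 ± 0.59 (adjusted p = 0.000859) and Pzp, a protease inhibitor, by 7.18 ± 0.93 (adjusted p = 0.00749). Lower in knockout were Abcc3 (-5.68 ± 0.23, adjusted p = 1.06e-05), the fatty acid hydroxylase Cyp4a14 (-5.61 ± 0.88, adjusted p = 0.0171) and the amino acid transporter Slc7a12 (-4.55 ± 0.42, adjusted p = 0.0011). Akr1c18, which inactivates progesterone, was lower (-3.83 ± 0.40, adjusted p = 0.00205), as was Scd1, the desaturase that makes oleate (-2.97 ± 0.29, adjusted p = 0.00161). The remaining named falls were Aadat (-2.90 ± 0.49), Igfals (-2.88 ± 0.24), Cdh6 (-2.85 ± 0.37), the solute carrier Slc17a2 (-2.59 ± 0.07) and Slc22a29 (-2.49 ± 0.35). Their adjusted p ran from 1.07e-06 for Slc17a2 to 0.0228 for Aadat. Tubule RNA was present in the extracts, with proximal tubule marker means of 15.18 to 15.68 in the untreated arrays. These differences are therefore not shown to lie in glomerular cells.

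**Figure D2:**
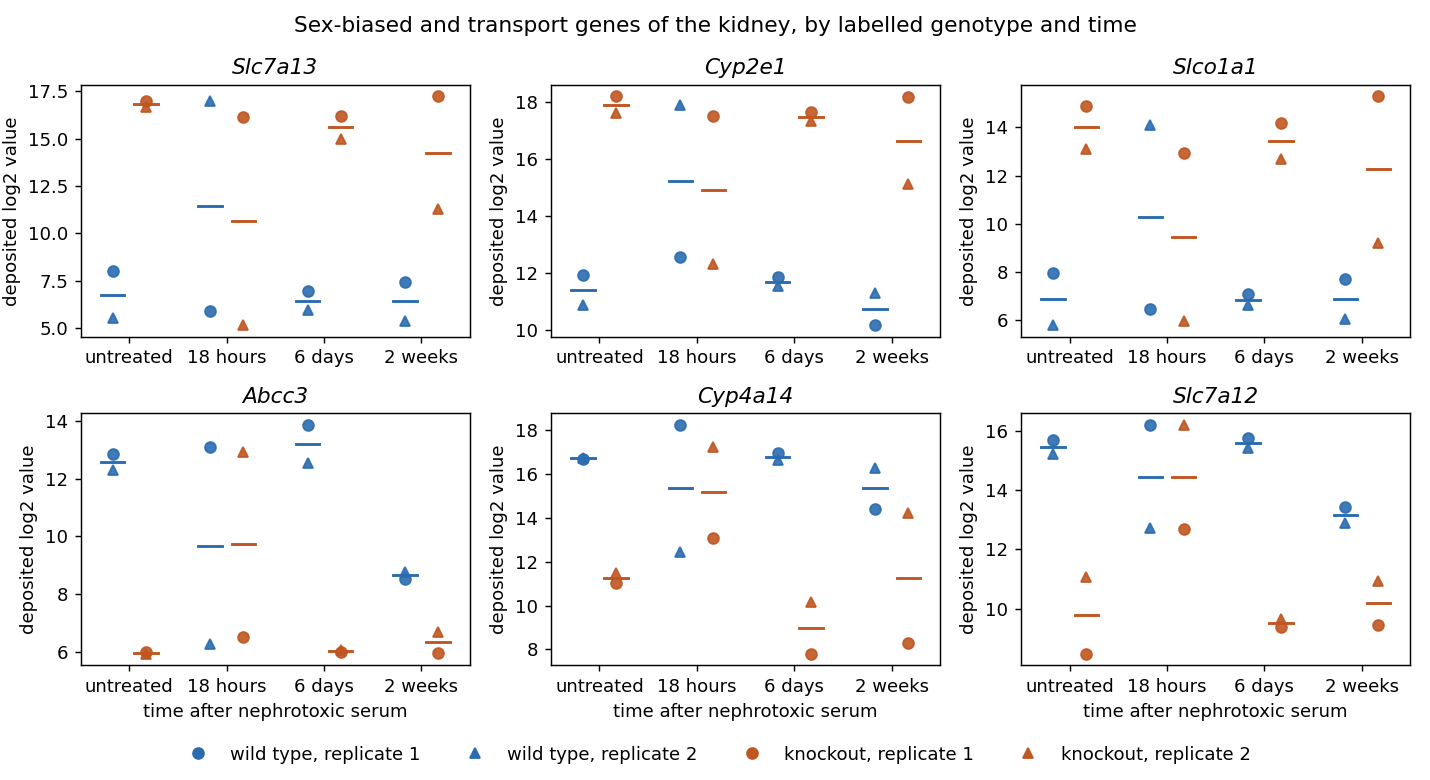
Deposited log2 values (vertical) of 6 genes in each array against time after serum (horizontal), with circles for replicate 1, triangles for replicate 2, bars for group means, and colour for the labelled genotype. Abcc3 stood at 12.57 in untreated wild type and 5.95 in untreated knockout, and at 18 hours replicates 2 of both genotypes carry values of the other genotype.

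Of the 15 male-biased kidney genes, 10 were higher and 0 lower in knockout over the 14 arrays (14 and 0 adjusted over the list alone). Their median was 4.76 (camera adjusted p = 3.94e-23; adjusted p = 0.149 with an estimated correlation; fry adjusted p = 0.0074). Over all 16 arrays 0 of the 15 passed over all genes and 13 were higher adjusted over the list alone. The median was 3.46 (camera adjusted p = 1.33e-15; adjusted p = 0.297 with an estimated correlation). Of the 5 female-biased genes, 3 were lower over the 14 arrays (4 adjusted over the list alone). Their median was -2.28 (camera adjusted p = 4.06e-05; adjusted p = 0.118 with an estimated correlation). Over all 16 arrays 0 of the 5 passed, with 3 lower and 1 higher adjusted over the list alone. The median was -1.51 (camera adjusted p = 0.00243; adjusted p = 0.297 with an estimated correlation).

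Most lipid lists held genes that differed in either direction, and camera called 1 list, eicosanoid metabolism, a call lost with an estimated correlation (adjusted p = 0.215). Values in this paragraph are from the 14 arrays, and whether glomerular or tubule cells carry the differences cannot be told. Of 21 genes of fatty acid and triglyceride synthesis 2 were higher and 2 lower (6 and 5 adjusted over the list alone). Scd1 and the elongase Elovl6 (-2.26 ± 0.11, adjusted p = 2.82e-05) were lower, and Mogat1, an acyltransferase of triglyceride synthesis, was higher (1.38 ± 0.27, adjusted p = 0.0445). Of 31 genes of PPAR signalling and targets 1 was higher and 3 were lower (4 and 6 alone). Cyp4a14 and the fatty acid binding protein gene Fabp1 (-1.64 ± 0.22, adjusted p = 0.00925) were lower. The fatty acid uptake receptor Cd36 differed by 2.16 ± 0.56 (adjusted p = 0.11). Of 24 fatty acid oxidation genes 1 was higher and 1 lower (1 and 1 alone). The peroxisomal oxidase Acox3 was higher (1.78 ± 0.26, adjusted p = 0.0119) and Hadha of the mitochondrial trifunctional protein was lower (-0.57 ± 0.11, adjusted p = 0.0412). Apoe was the 1 gene lower among 18 for cholesterol efflux and lipoproteins (-1.17 ± 0.23, adjusted p = 0.0399; 1 higher and 3 lower alone). In cholesterol synthesis and uptake 0 of 17 passed, and 0 alone. Of 24 eicosanoid genes 3 were higher and 3 lower (4 and 11 alone). The epoxide hydrolase Ephx2 was higher (1.94 ± 0.34, adjusted p = 0.027) and Hpgd, which inactivates prostaglandins, was lower (-1.32 ± 0.17, adjusted p = 0.00805). Of 29 retinoid genes 2 were higher and 1 lower (3 and 1 alone). Adh1, a retinol and alcohol dehydrogenase, was higher (2.85 ± 0.40, adjusted p = 0.0112). Camera adjusted p was 0.944 for synthesis, 0.831 for PPAR, 0.0545 for oxidation, 0.448 for cholesterol synthesis, 0.0785 for efflux and 0.874 for retinoids. It was 0.0165 for eicosanoids (median -0.24).

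Interferon response genes were lower in knockout as a group. Of 21, 3 were lower over the 14 arrays (16 adjusted over the list alone), led by the GTPase gene Gbp3 (-1.83 ± 0.19, adjusted p = 0.00191). Their median was -0.46 (camera adjusted p = 1.76e-15; adjusted p = 0.149 with an estimated correlation; fry adjusted p = 0.00785). Over all 16 arrays the interferon median was -0.38, with 16 lower adjusted over the list alone (camera adjusted p = 6.04e-16; adjusted p = 0.29 with an estimated correlation). Of 23 macrophage and monocyte markers 2 were lower (6 alone; median -0.21), among them the signalling adaptor Tyrobp (-0.61 ± 0.09, adjusted p = 0.0106). The macrophage mean was 6.26 and 6.17 in untreated wild type and 6.29 and 6.17 in untreated knockout. At 6 days it was 6.70 and 6.67 against 6.41 and 6.54, and at 2 weeks 7.01 and 7.05 against 6.20 and 6.53. The 6.20 is knockout 2 weeks replicate 1, which lacks the response of its replicate, so averages over the 14 arrays rest partly on it. Of 25 matrix genes 2 were lower (4 alone; median -0.30), fibronectin Fn1 (-2.41 ± 0.38, adjusted p = 0.0171) and Thbs1 (-1.52 ± 0.25, adjusted p = 0.0215). C4b (1.55 ± 0.16, adjusted p = 0.00191) and C4a (0.83 ± 0.09, adjusted p = 0.00323) were the 2 higher among 18 complement genes. The extracts held tubule RNA too, with proximal tubule means of 15.18 to 15.68 in the untreated arrays. The podocyte mean was 9.83 and 9.16 in untreated wild type and 8.81 and 9.12 in untreated knockout. Over the 14 arrays a lower share of glomerular RNA in knockout and falls within glomerular cells cannot be told apart, so such falls are not shown. Marker lists of glomerular cells lay lower too, as given next. Their means in knockout 2 weeks replicate 1 (podocyte 8.675, endothelial 8.318, mesangial 7.85) were the lowest of all 16 arrays. Camera also called podocyte (median -0.60), endothelial (-0.61), mesangial (-0.59) and distal nephron markers (-0.37) and MHC class II genes (-0.25) lower, calls lost with an estimated correlation. In these lists 1 member passed, the podocyte matrix gene Npnt (-1.56 ± 0.25, adjusted p = 0.0201). Camera adjusted p was 2.62e-06 for macrophages, 2.22e-08 for matrix, 7.69e-07 for podocytes, 0.000142 for endothelium, 3.05e-06 for mesangium, 4.06e-05 for distal nephron and 0.00152 for MHC class II. With an estimated correlation the adjusted p ran from 0.149 for macrophages to 0.608 for endothelium. Oxidative phosphorylation had a median of 0.13 with 0 of 26 passing (camera adjusted p = 0.0399; adjusted p = 0.812 with an estimated correlation). The proximal tubule median was 0.29 (camera adjusted p = 0.111), with Acsm2 higher (2.75 ± 0.43, adjusted p = 0.0166). Of the 10 oestrogen receptor genes and classical targets, Esr1 was higher (0.70 ± 0.09, adjusted p = 0.00554) and Igf1 lower (-0.37 ± 0.07, adjusted p = 0.0377), with a median of -0.02.

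The next comparison sets the genotypes against each other at each time. In untreated mice limma called 0 genes over all 16 arrays (1564 at an unadjusted p under 0.05). The smallest p-values were those of the lipid-binding gene Sec14l3 (-2.66 ± 0.37), Aldh3b2 (-0.99 ± 0.15) and Lgals12 (-1.12 ± 0.17), each with an adjusted p of 0.397. The median of the male-biased genes was 5.84 (10 of 15 higher adjusted over the list alone; camera adjusted p = 2.98e-13; adjusted p = 0.643 with an estimated correlation). Fitting only the groups compared gave 124 genes in untreated mice, 80 higher and 44 lower. The untreated arrays are the same in these fits and in that of the 14 arrays, so only the spread differs. With all 16 arrays the shared spread includes the gap between the 18-hour replicates. The SE of the untreated Esr1 difference was 0.23 with them and 0.15 over the 14 arrays. The 16-array count and the order of its smallest p-values thus depend on arrays of another time. Over the 14 arrays 51 genes were called in untreated mice, 12 higher and 39 lower. These included Ugt2b37 (8.20 ± 0.98, adjusted p = 0.0189) and Cyp2j13 (7.89 ± 0.71, adjusted p = 0.00527) on the higher side. On the lower side they included Abcc3 (-6.62 ± 0.40, adjusted p = 0.000476), the acyl-CoA thioesterase gene Acot3 (-3.44 ± 0.34, adjusted p = 0.00694) and Dio1, which activates thyroid hormone (-3.06 ± 0.39, adjusted p = 0.0255). At 18 hours 0 genes were called over all 16 arrays (707 at an unadjusted p under 0.05, smallest adjusted p = 1 for Krtap4-1, Sft2d2 and Csn1s2b). Over the 14 arrays 12 were called, among them Slc17a2 (-3.16 ± 0.18, adjusted p = 0.000721) and Elovl6 (-3.15 ± 0.27, adjusted p = 0.00603). At this time 1 array per genotype then remained, so the spread came from the other groups alone. Across genes, which are not independent replicates, the untreated and 6-day differences had r = 0.75. The untreated and 18-hour differences had r = -0.133 over 16 arrays and 0.616 over 14.

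At 6 days the complement genes C4b and C4a were higher in knockout, the only 2 genes called over all 16 arrays (1457 at an unadjusted p under 0.05). C4b stood at 6.48 ± 0.57 in wild type and 10.20 ± 0.46 in knockout (SD, n = 2), a difference of 3.71 ± 0.34 (SE, adjusted p = 0.00989). C4a differed by 1.95 ± 0.19 (adjusted p = 0.0102). The paralogs are nearly identical in sequence, so 1 source of signal for both probesets is not excluded. Leaving out 1 of the 4 arrays at this time gave 0 to 1 called genes, and the 14 arrays gave 71 (20 higher, 51 lower), both C4 genes among them. Fitting only the groups compared gave 113 (52 higher, 61 lower). Of the 71, Olfm4, a secreted glycoprotein gene, was higher (2.49 ± 0.38, adjusted p = 0.0428). The peroxisomal hydroxyacid oxidase gene Hao2 (-3.86 ± 0.34, adjusted p = 0.00249) and Scd1 (-3.98 ± 0.52, adjusted p = 0.0229) were lower.

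At 2 weeks macrophage genes such as Lyz2 and Tyrobp were lower in knockout, and Usp2, Klf9 and Pex11a were higher. Limma called 55 genes over all 16 arrays, 11 higher and 44 lower (5841 at an unadjusted p under 0.05), 9 of them numbered transcripts or pseudogenes. The lower genes included the macrophage lysozyme Lyz2 (-2.82 ± 0.41, adjusted p = 0.0357), Tyrobp (-1.39 ± 0.17, adjusted p = 0.0231), the beta-glucan receptor Clec7a (-1.42 ± 0.20, adjusted p = 0.0299) and Ms4a6c (-1.36 ± 0.22, adjusted p = 0.0421). Also lower were Ncam1 (-1.43 ± 0.23, adjusted p = 0.0472) and Gprin3 (-1.34 ± 0.22, adjusted p = 0.0472). The higher genes included the deubiquitinase gene Usp2 (1.88 ± 0.26, adjusted p = 0.0299), Sypl2 (1.81 ± 0.27, adjusted p = 0.0373) and Alas1 of haem synthesis (1.56 ± 0.26, adjusted p = 0.0495). They also included Pex11a of peroxisome division (1.38 ± 0.18, adjusted p = 0.0299) and the glucocorticoid-induced Klf9 (1.38 ± 0.16, adjusted p = 0.0231). Susd3, Prr5 and Adamts6 were higher by 1.21, 1.03 and 0.99. Of 23 macrophage markers 3 were lower (15 adjusted over the list alone). Their median was -0.70 (camera adjusted p = 1.31e-09; adjusted p = 0.102 with an estimated correlation; fry adjusted p = 0.00221). The medians were -0.73 for interferon response (16 of 21 lower alone), -0.98 for MHC class II (8 of 9), -0.99 for matrix (17 of 25) and -0.79 for cell cycle (19 of 27). They were 0.81 for proximal tubule markers (4 of 21 higher alone), 0.77 for fatty acid oxidation and 0.91 for oxidative phosphorylation. Camera called 19 lists and 0 held with an estimated correlation. Without knockout 2 weeks replicate 1 limma called 0 genes, with 1 knockout array left at that time. Of the 55, 7 were also called over the 14 arrays and 2 over the 13, among them Sypl2 (1.65, adjusted p = 0.0467 over the 13). Leaving out knockout replicate 2 gave 5331 genes, wild type replicate 1 gave 4480 and wild type replicate 2 gave 9. With knockout replicate 2 left out, only the array that lacks the response stands for knockout, so that count mixes response with genotype. The tubule covariate, array weights, testing all probesets and fitting only the groups compared each gave 0. Quantile normalization gave 26, 12 higher and 14 lower, and centring 18, 9 each way.

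Over all 16 arrays the most genes responding to serum were called in wild type at 2 weeks, where tubule injury, cell division and macrophage genes rose and genes of the proximal tubule, of oxidative phosphorylation and of fatty acid oxidation fell. Limma called 2424 genes, 1450 higher and 974 lower (9289 at an unadjusted p under 0.05), 617 of them numbered transcripts, pseudogenes, small RNAs or members of large receptor families. Havcr1 rose by 6.84 ± 1.41 (adjusted p = 0.0229), from 6.05 ± 0.02 to 12.89 ± 0.47 (SD, n = 2). The protease inhibitor gene Serpina10 rose by 5.48 ± 1.17 (adjusted p = 0.0255) and the adhesion molecule Vcam1 by 4.00 ± 1.0 (adjusted p = 0.0378). D17H6S56E-5 rose by 4.10 ± 0.79, the vasodilator adrenomedullin Adm by 3.92 ± 0.77, the thrombin receptor F2r by 3.65 ± 0.91, and the proliferation marker Mki67 by 3.51 ± 0.81. Tenascin Tnc rose by 3.14 ± 0.55, Ccn1 by 3.11 ± 0.73 and Lyz2 by 3.07 ± 0.41. Adjusted p in this group ran from 0.00738 for Lyz2 to 0.0377 for F2r. The falls included Akr1c18 (-6.17 ± 1.32, adjusted p = 0.0255) and the carriers Slc22a26 (-5.20 ± 0.96, adjusted p = 0.0175) and Slc13a3 (-3.64 ± 0.64, adjusted p = 0.0156). Also lower were Cyp2a4 (-4.41 ± 0.94, adjusted p = 0.0252), the distal tubule growth factor Egf (-3.96 ± 0.97, adjusted p = 0.0356) and Rnf24 (-3.89 ± 0.71, adjusted p = 0.0168).

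**Figure D3:**
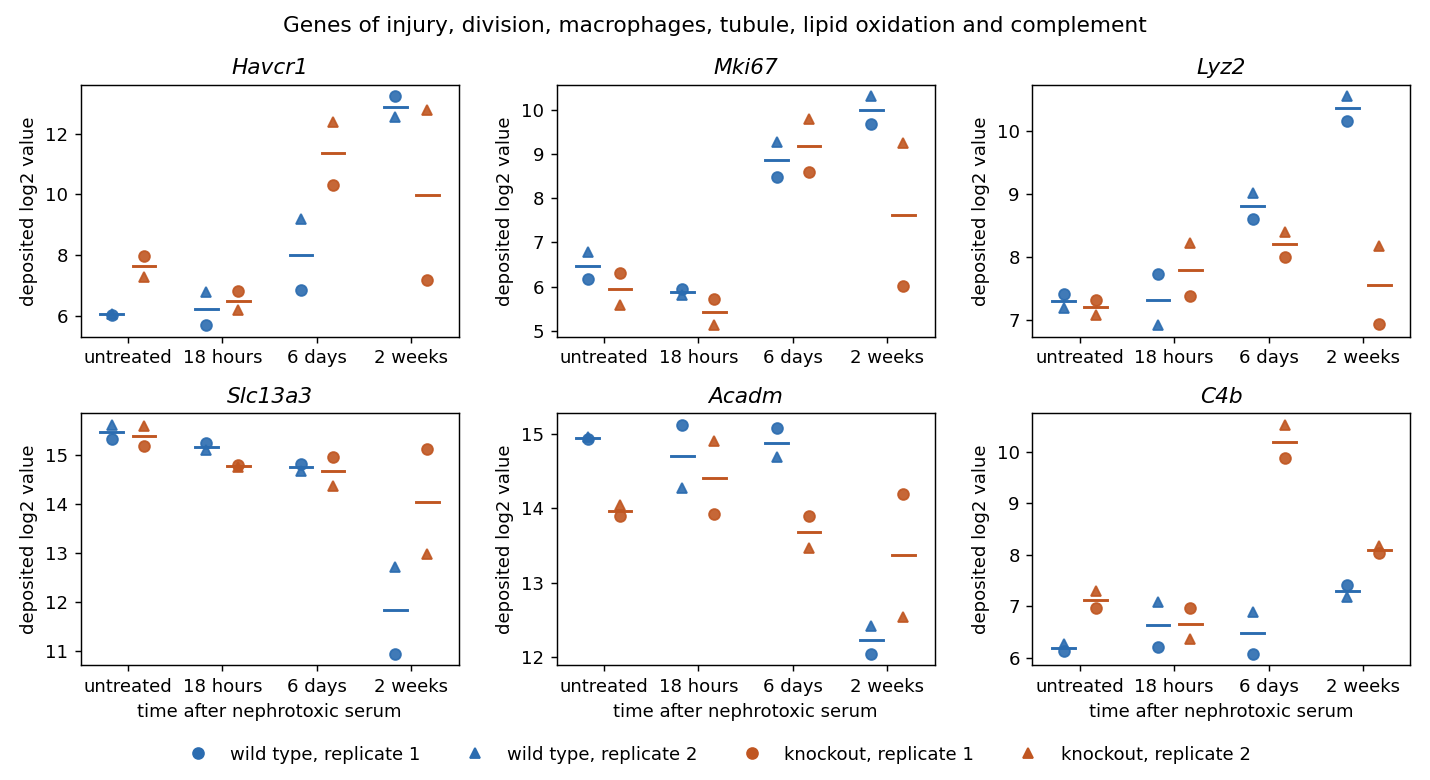
Deposited log2 values (vertical) of 6 genes in each array against time after serum (horizontal), with circles for replicate 1, triangles for replicate 2, bars for group means, and colour for the labelled genotype. Havcr1 reached 12.89 in wild type at 2 weeks and was 7.17 and 12.77 in the knockout arrays of that time, and C4b stood at 10.20 in knockout at 6 days.

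Lists of oxidative phosphorylation, fatty acid oxidation, PPAR and fatty acid synthesis genes were lower in wild type at 2 weeks. Of 26 oxidative phosphorylation genes 17 fell (23 adjusted over the list alone), with a median of -1.43, led by Cyc1 (-2.27 ± 0.43) and Cox5b (-2.04 ± 0.36). Of 24 fatty acid oxidation genes 11 fell (22 alone), with a median of -1.40. Among them were the medium-chain dehydrogenase Acadm (-2.71 ± 0.50, adjusted p = 0.0171) and Echs1 (-1.72, adjusted p = 0.0286). Camera adjusted p was 9.43e-19 and 5.53e-17, and 0.151 for both with an estimated correlation. Of 31 PPAR genes 8 fell (15 alone; median -1.25; camera adjusted p = 1.82e-09). They included the gluconeogenic Pck1 (-3.35 ± 0.68, adjusted p = 0.0226), lipoprotein lipase Lpl (-2.66, adjusted p = 0.0479) and Fabp3 (-2.45, adjusted p = 0.0289). Of 21 synthesis genes 2 fell (10 alone; median -0.72; camera adjusted p = 1.05e-08). These last 2 lists held with an estimated correlation, at adjusted p = 0.0204 and 0.0381. Cholesterol synthesis and uptake had a median of -0.72 with 0 of 17 passing (6 alone; camera adjusted p = 3e-06; adjusted p = 0.229 with an estimated correlation). Cholesterol efflux (1 up and 1 down of 18, median 0.18), retinoid metabolism (2 up and 2 down of 29, median 0.18) and eicosanoid metabolism (2 up of 24, median 0.15) were not called. In them Rdh16, a retinol dehydrogenase, fell (-2.23 ± 0.29, adjusted p = 0.00653) and the prostaglandin D synthase Ptgds rose (1.29, adjusted p = 0.023).

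Inflammatory and dividing-cell genes rose in the same arrays, though none of their list calls held with an estimated correlation. The adjusted p was then 0.0796 for macrophages and ran from 0.151 to 0.255 for the other lists that camera called here. Of 23 macrophage markers 15 rose (20 adjusted over the list alone; median 0.75), with Tyrobp at 1.31 ± 0.17 and the integrin Itgam at 1.20 ± 0.20 (adjusted p = 0.0128). Camera gave this list an adjusted p of 3.67e-09 (fry adjusted p = 0.000373). Of 27 cell cycle genes 21 rose (24 alone; median 1.30; camera adjusted p = 1.31e-11), including the topoisomerase Top2a (2.34 ± 0.46). Of 24 acute phase and injury genes 7 rose (16 alone; median 1.41; camera adjusted p = 3e-06). Of 25 chemokines and cytokines 12 rose (16 alone; median 0.67; camera adjusted p = 7.09e-07). They included the monocyte attractant Ccl2 (2.22 ± 0.35, adjusted p = 0.0118) and the macrophage growth factors Il34 (2.52, adjusted p = 0.0294) and Csf1 (2.26, adjusted p = 0.0488). Of 9 MHC class II genes 6 rose (7 alone; median 1.09; camera adjusted p = 2.28e-05), with H2-Ab1 at 2.54 ± 0.40. Of 21 interferon genes 9 rose (13 alone; median 0.55; camera adjusted p = 8.26e-06). Matrix genes followed (11 of 25 rose, 18 up and 1 down alone; median 1.16; camera adjusted p = 4.58e-06), as did complement (5 of 18 rose, 13 alone; median 0.59; camera adjusted p = 0.000963). So did immediate early genes (9 of 20 rose, 15 alone; median 0.70; camera adjusted p = 1.31e-05) and T and NK cell markers (1 of 17 rose, 1 alone; median 0.27; camera adjusted p = 0.00683). Neutrophil (median 0.25) and B cell markers (0.17) and the oestrogen receptor list (0.13) were not called.

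Markers of the tubule moved with these lists. Of 21 proximal tubule markers 10 fell (21 adjusted over the list alone; median -2.13; camera adjusted p = 5.18e-15; adjusted p = 0.151 with an estimated correlation). Their mean was 15.18 and 15.68 in the untreated arrays and 12.78 and 13.88 at 2 weeks. Of 17 distal nephron markers 1, the calcium-binding Pvalb, fell (-1.94 ± 0.44, adjusted p = 0.0291), and 7 fell adjusted over the list alone (median -1.24; camera adjusted p = 0.000153; adjusted p = 0.314 with an estimated correlation). Podocyte (median 0.55), endothelial (0.76) and mesangial markers (0.67) were not called, though the endothelial Plvap fell (-1.54 ± 0.37, adjusted p = 0.0353). Camera called lower the 12 adipocyte markers (median -0.31; adjusted p = 7.7e-05; adjusted p = 0.229 with an estimated correlation). It called lower the 5 female-biased genes (-2.29; adjusted p = 0.00154; adjusted p = 0.151 with an estimated correlation) and the 15 male-biased genes (-0.35; adjusted p = 0.0408; adjusted p = 0.643 with an estimated correlation). Of the latter the androgen-regulated Kap fell (-2.90 ± 0.52, adjusted p = 0.016). The median of all genes was 0.13 in this comparison, -0.01 after quantile normalization and -0.08 after centring. The balance of higher and lower genes turned with these, to 486 higher and 611 lower of 1097 and to 566 higher and 2725 lower of 3291. It turned too without the genes below median brightness (607 higher, 1187 lower) and when only the groups compared were fitted (291 higher, 328 lower). Array weights gave 277 genes, fewer than the 666 they gave in knockout at 6 days. With a covariate for the tubule share 610 genes were called, 540 higher and 70 lower, and the oxidative phosphorylation median was -0.45. Without wild type untreated replicate 2 limma called 0 genes, without untreated replicate 1 it called 32, without 2 weeks replicate 2 it called 231 and without 2 weeks replicate 1 it called 7438. The 14 arrays gave 859 (779 of them among the 2424) and the 13 arrays 3884 (2183 of them).

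**Figure D4:**
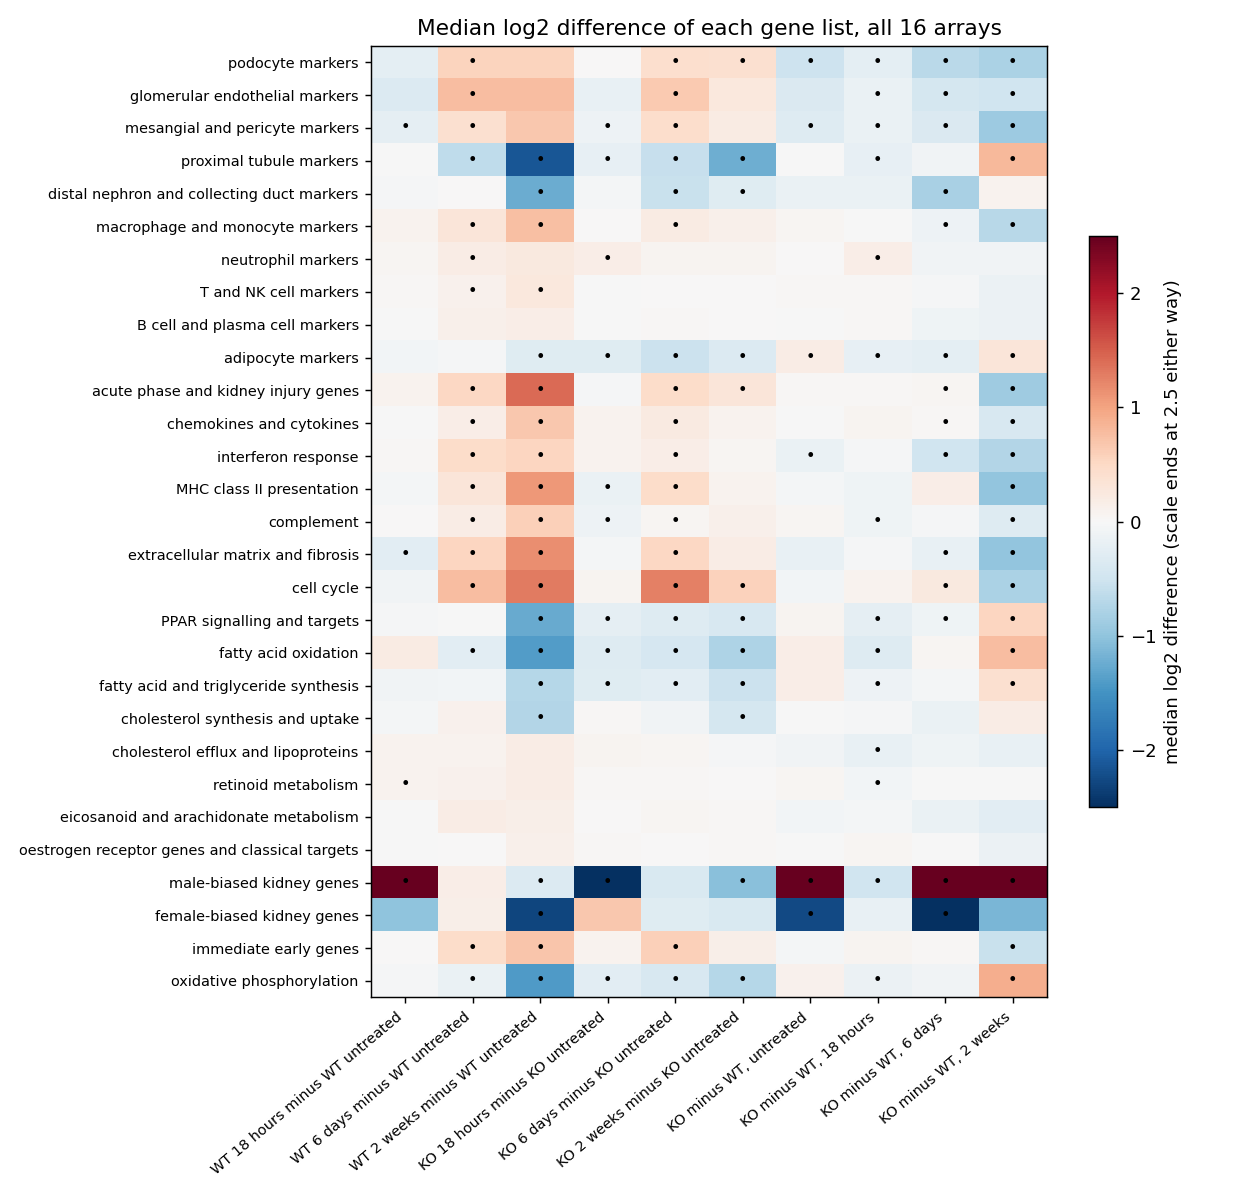
Median log2 difference of 29 gene lists (vertical) in 10 comparisons over all 16 arrays (horizontal), with red for higher, blue for lower, a colour scale that ends at 2.5 in either direction, and a dot where the camera adjusted p was under 0.05 with the preset correlation. Fatty acid oxidation had a median of -1.40 and cell cycle 1.30 in wild type at 2 weeks, and the male-biased genes had a median of 5.84 in untreated knockout against wild type.

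Earlier after serum, cell cycle genes led in wild type at 6 days and the chaperones Hyou1 and Hspa5 at 18 hours, without a gene that passed. At 6 days limma called 0 genes (2106 at an unadjusted p under 0.05), led by the histone H2ac15 (1.97 ± 0.23, adjusted p = 0.099), the actin-binding Tagln (3.82 ± 0.56, adjusted p = 0.155) and Rhoc (2.02 ± 0.30, adjusted p = 0.155). Of 27 cell cycle genes 19 were higher adjusted over the list alone (median 0.76; camera adjusted p = 1.38e-18; adjusted p = 0.328 with an estimated correlation). Higher in the same way were 5 of 20 immediate early genes (median 0.45; camera adjusted p = 2.31e-10; adjusted p = 0.328 with an estimated correlation) and 7 of 21 interferon genes (median 0.47; camera adjusted p = 9.1e-10; adjusted p = 0.328 with an estimated correlation). At 18 hours limma called 0 genes (1186 at an unadjusted p under 0.05), led by the endoplasmic reticulum chaperones Hyou1 (1.26 ± 0.18) and Hspa5 (1.61 ± 0.24) and the sulfotransferase Sult1d1 (1.78 ± 0.29), each with an adjusted p of 0.466. Wild type replicate 2 at 18 hours carries the knockout pattern (genotype score 1.07), so the 18-hour group mean mixes 2 patterns. A chaperone response of wild type at 18 hours is therefore not shown. Array weights gave 65 genes at 6 days and the tubule covariate gave 5. The 13 arrays gave 2, Adm (4.71) and the cholesterol hydroxylase Ch25h (1.51).

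In knockout mice C4b (3.07 ± 0.34) and C4a (1.61 ± 0.19) rose from untreated to 6 days, each with an adjusted p of 0.0469, and were 2 of the 4 genes called (2250 at an unadjusted p under 0.05). Of 27 cell cycle genes 25 were higher adjusted over the list alone (median 1.25; camera adjusted p = 7.85e-34; adjusted p = 0.181 with an estimated correlation). Of 24 injury genes 5 were higher in this way (median 0.46; camera adjusted p = 6.15e-08; adjusted p = 0.181 with an estimated correlation). None of the 24 passed over all genes, and the largest differences among them were Fgg at 7.32 ± 1.37 (adjusted p = 0.156), Fga at 4.36 ± 0.71 (adjusted p = 0.132) and Fgb at 3.87 ± 0.72 (adjusted p = 0.156). At 2 weeks 33 genes rose and 0 fell (2488 at an unadjusted p under 0.05). Of these 31 were numbered transcripts, and the others were Zfp979 (0.96 ± 0.13, adjusted p = 0.0189) and the metalloprotease Adamts6 (0.94 ± 0.15, adjusted p = 0.044). The proximal tubule median was -1.22 (camera adjusted p = 1.52e-10; adjusted p = 0.391 with an estimated correlation). At 18 hours 0 genes were called (1216 at an unadjusted p under 0.05), led by the vitamin D hydroxylase Cyp24a1 (-3.66 ± 0.63), Thrsp (-1.38 ± 0.24) and the apelin receptor Aplnr (-1.22 ± 0.22), each with an adjusted p of 1. Knockout replicate 2 at this time carries the wild type pattern (genotype score 0.0203), so this group mean mixes 2 patterns as well. Leaving out 1 of the 4 arrays compared gave 0 to 1 genes at 6 days and the 14 arrays gave 0, against 666 with array weights and 46 over the 13 arrays. Without knockout 2 weeks replicate 1 the 2-week count was 1598 and over the 13 arrays 1312 (486 higher, 826 lower), with Havcr1 at 5.16 ± 0.98 and Slc7a13 at -5.55 among the largest. In both counts 1 knockout array stands for 2 weeks, and the spread came from the other groups. Without replicate 2 it was 731, without untreated replicate 1 it was 10 and without untreated replicate 2 it was 2. The tubule covariate gave 575 (570 higher, 5 lower), centring 19, quantile normalization 15, array weights 4 and fitting only the groups compared 0.

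The last comparison asks whether the response to serum differed between the genotypes. Over all 16 arrays limma called 0 genes at 18 hours (1108 at an unadjusted p under 0.05), 0 at 6 days (395), 0 at 2 weeks (2244) and 0 in the F test over the 3 times (1861). C4b had the smallest p at 6 days, with a knockout response larger by 2.78 ± 0.49 (adjusted p = 1), followed by C4a (1.45 ± 0.27) and Fam47c (-0.88 ± 0.21). At 2 weeks the smallest p-values were those of the macrophage Ly86 (-0.98 ± 0.14), Sec14l3 (3.24 ± 0.52) and the interferon regulator Irf1 (-1.03 ± 0.17), each with an adjusted p of 0.431. At 18 hours, where both replicates 2 carry the pattern of the other genotype, they were those of Aldh3b2 (1.18 ± 0.21), Nt5e (-2.15 ± 0.42) and Sft2d2 (-1.11 ± 0.23). The macrophage list had a smaller response in knockout at 2 weeks, with a median of -0.71 and 11 of 23 members lower adjusted over the list alone. Camera gave it an adjusted p of 7.85e-11, with adjusted p = 0.0604 with an estimated correlation and a fry adjusted p of 0.0169. MHC class II genes had a median of -0.94 (6 of 9 lower alone), proximal tubule markers 0.91, oxidative phosphorylation 0.72 and PPAR genes 0.48 (adjusted p = 0.0604 with an estimated correlation for the last). Across genes the wild type and knockout responses had r = -0.206 at 18 hours (0.103 over the 14 arrays), 0.68 at 6 days and 0.666 at 2 weeks. At 2 weeks 27 genes were called in both, and 26 of these were numbered transcripts, which could mark a batch of 2-week arrays. Independent calls would give 2.65. Both comparisons share each gene's variance in 1 fit, so the calls are not independent and the excess over 2.65 is not a measure of agreement. The 14 arrays gave 1 gene at 2 weeks, Slc17a2 (2.13 ± 0.18, adjusted p = 0.0223). Without wild type 2 weeks replicate 1 the count at 2 weeks was 1664 and without knockout 2 weeks replicate 2 it was 535. With the latter array left out, only the array that lacks the response stands for knockout at 2 weeks. That count therefore reflects its lack of response as well as genotype.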

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

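The tests of explanations for the 3 patterns at the end of this part, and the 13-array setting, were chosen only after the results were seen.

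The macrophage and monocyte markers responded less to serum in knockout than in wild type at 2 weeks, by a test of the difference itself. Their median difference of responses was -0.711 over 23 genes (fry adjusted p = 0.0169; camera adjusted p = 7.85e-11; adjusted p = 0.0604 with an estimated correlation), and over the 13 arrays without knockout 2 weeks replicate 1 it was -0.48 (fry adjusted p = 0.0467; adjusted p = 0.254 with an estimated correlation). In that setting knockout at 2 weeks is 1 array with its spread taken from other groups, so its p adds little. Proximal tubule markers (0.913), MHC class II genes (-0.94) and oxidative phosphorylation (0.72) moved in the same contrast over 16 arrays. The macrophage mean of knockout 2 weeks replicate 1 was 6.196, against 6.292 and 6.169 in untreated knockout, so over 16 arrays the list does not stand apart from the lack of response in that array.

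Among probesets with no gene symbol, which the gene tests do not use, 468 of 39938 (1.17%) were called in wild type at 2 weeks against untreated, 357 higher (median 0.979) and 111 lower (median -1.36), against 2.34% of genes in the same fit of all probesets, whose adjustment covers more tests than the gene test does.

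The arrays given as 18 hours replicate 2 in wild type and in knockout carry the genotype pattern of the other genotype. An exchange of the 2 labels may account for this: on 449 genes chosen from the other times the wild type array scored 1.07 and the knockout array 0.0203, where 0 is wild type and 1 knockout, and their replicates scored 0.0273 and 0.938. Exchanging these 2 labels gave 1583 called genes in the genotype average. The other 15 exchanges of 1 wild type and 1 knockout array within a time gave at most 42 and the labels as given 0. The 2 arrays were picked by their values, and exchanges at other times leave both as labelled. These counts therefore add no support for an exchange beyond the scores. A different tubule share is argued against as the source of the pattern, since the proximal tubule median moved from replicate 1 to 2 by 0.019 in wild type (SD over markers 0.82) and 0.0405 in knockout (SD 0.79), while genes higher in knockout moved by 1.01 and -0.977. Distal nephron means moved with the pattern (11.949 to 10.94 in wild type, 10.999 to 11.641 in knockout), as did podocyte means (9.563 to 8.882, 8.886 to 9.122), so a difference of composition beside it stays open, as does a real difference between mice of 1 group, and the labels were kept for want of a record of the genotypes.

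Knockout 2 weeks replicate 1 lacks the nephritis response of its replicate. A higher tubule share is neither shown nor excluded: its proximal tubule mean of 15.26 lay within the range of the untreated and 18-hour knockout arrays (15.18 to 15.59), with 388 response genes at a median position of -0.0433, where 0 is untreated knockout and 1 is replicate 2, but its podocyte (8.675), endothelial (8.318) and mesangial (7.85) means were the lowest of all 16 arrays. Whether it is an array of an earlier time cannot be told: 95 numbered transcripts that are high in the other 2-week arrays stood at a median position of 0.701 in it, with 61 above the middle, against at most 21 in any array of an earlier time. This argues against an earlier time only if the numbered transcripts mark time and not a batch of 2-week arrays, and the labels give no batch. A mouse in which nephritis did not develop stays open as well.

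Metabolic and tubule genes were lower in wild type at 2 weeks. A lower share of tubule RNA in those extracts and lower expression within tubule cells cannot be told apart: distal nephron markers fell less than proximal markers by 0.891, close to the SDs over members of 0.745 and 0.859. With the tubule covariate the oxidative phosphorylation median was -0.451 (SD over members 0.48) against -1.43 without it. The covariate is itself built from tubule markers, which keeps this open, and either could contribute.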

How the results depend on the processing

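Settings that leave out 18-hour arrays or knockout 2 weeks replicate 1 together were chosen after the data were seen, and all other settings were fixed beforehand. No named gene reversed its direction with a call under any setting. Leaving out the lowest quartile of genes by brightness, averaging probesets and a robust variance trend moved no count of called genes by more than 1.5 times. The deposited values give no background level, so what dim signal limits is known only from the filters on brightness.

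With genes below the median brightness left out, 17 genes were called between genotypes at 2 weeks, 12 in knockout at 6 days and 1794 in wild type at 2 weeks (607 higher, 1187 lower). With all probesets tested, these were 0 and 0, and wild type at 2 weeks had 1235, where more tests enter the adjustment. Quantile normalization gave 26 between genotypes at 2 weeks (12 higher, 14 lower), 1097 in wild type at 2 weeks (486 higher, 611 lower), 2 in knockout at 6 days and 15 in knockout at 2 weeks. Centring gave 18 (9 higher, 9 lower) between genotypes at 2 weeks, 3291 (566 higher, 2725 lower) in wild type at 2 weeks and 19 in knockout at 2 weeks. Without the variance trend 34 genes (11 higher, 23 lower) were called between genotypes at 2 weeks. Array weights gave 3 between genotypes untreated, 4 at 6 days and 0 at 2 weeks, 65 in wild type at 6 days, 277 in wild type at 2 weeks, 666 in knockout at 6 days and 4 in knockout at 2 weeks. The tubule covariate gave 0 between genotypes at 2 weeks, 5 in wild type at 6 days, 610 (540 higher, 70 lower) in wild type at 2 weeks, 11 in knockout at 6 days and 575 (570 higher, 5 lower) in knockout at 2 weeks. Fitting only the groups compared gave 124 (80 higher, 44 lower) between genotypes untreated, 113 (52 higher, 61 lower) at 6 days and 0 at 2 weeks, 619 (291 higher, 328 lower) in wild type at 2 weeks, and 0 in knockout at 6 days and at 2 weeks, from fewer arrays. The cause of the other moves was not tested.

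A replicate block, an additive term for the replicate number of the labels, gave 35 genes between genotypes at 2 weeks (8 higher, 27 lower) and moved no other count of called genes by more than 1.5 times. The numbers do not pair the arrays: across the 28 pairs of groups the correlation of replicate differences over genes ran from -0.679 to 0.593, with a median of 0.0402, and 11 were over 0.1.

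Without both 18-hour replicate 2 arrays, the genotype average had 519 genes and an Esr1 difference of 0.698, the genotype difference had 51 untreated, 12 at 18 hours, 71 at 6 days and 11 at 2 weeks, wild type at 2 weeks had 859, knockout had 0 at 6 days and 18 at 2 weeks, and the difference of responses had 1 at 2 weeks and 1 in the F test. Without knockout 2 weeks replicate 1 as well, these were 786, 0.704, 190, 111, 222, 6, 3884, 46, 1312, 0 and 0, and wild type at 6 days had 2. Without any 18-hour array the genotype average had 449 genes and an Esr1 difference of 0.669. At 18 hours the first 2 settings keep 1 array per genotype, and the second keeps 1 knockout array at 2 weeks, so counts for these groups (12 and 111 at 18 hours) take their spread from other groups. These settings differ from the 16 arrays by construction in the arrays they hold.

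Leaving out 1 array at a time gave ranges of 0.462 to 0.632 for the Esr1 difference (adjusted p from 0.0324 to 0.525), and of called genes 0 to 2196 for the genotype average (2196 without knockout 2 weeks replicate 2, 46 without wild type 18 hours replicate 2, 40 without wild type 2 weeks replicate 1 and 2 without knockout 18 hours replicate 2). The genotype difference ranged from 0 to 0 untreated, 0 to 1 at 18 hours, 0 to 1 at 6 days and 0 to 5331 at 2 weeks. Wild type ranged from 0 to 0 at 18 hours, 0 to 0 at 6 days and 0 to 7438 at 2 weeks, and knockout from 0 to 2, 0 to 1 and 2 to 1598. The difference of responses ranged from 0 to 0 at 18 hours, 0 to 0 at 6 days and 0 to 1664 at 2 weeks, and the F test from 0 to 560.

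Of the lists called by camera over all 16 arrays, an estimated correlation left 2 in wild type at 2 weeks and 0 in every other contrast. Camera, an estimated correlation and fry called 15, 0 and 2 lists in the genotype average, 6, 0 and 0 untreated, 14, 0 and 0 at 18 hours, 14, 0 and 0 at 6 days and 19, 0 and 10 at 2 weeks between genotypes. In wild type they called 4, 0 and 0 at 18 hours, 17, 0 and 0 at 6 days and 20, 2 and 18 at 2 weeks, and in knockout 11, 0 and 0, 19, 0 and 0 and 12, 0 and 0. In the difference of responses they called 9, 0 and 0, 7, 0 and 0 and 17, 0 and 1. Without both 18-hour replicate 2 arrays camera called 14 lists in the difference of responses at 18 hours. Without knockout 2 weeks replicate 1 as well it called 15 there and 9 at 2 weeks, 11 between genotypes at 2 weeks and 20 in knockout at 2 weeks.

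Among named genes, leaving out 1 array kept the side of the threshold in 1392 gene values, ended the call in 202, made a call in 96 and moved 2. The tubule covariate kept 165, ended 63, made 1 and moved 8. Array weights kept 160, ended 51 and made 26. Leaving out both 18-hour replicate 2 arrays kept 152, ended 41 and made 44, and leaving out knockout 2 weeks replicate 1 as well kept 147, ended 14, made 75 and moved 1. Fitting only the groups compared kept 191, ended 38 and made 8, testing all probesets kept 197 and ended 40, quantile normalization kept 219 and ended 18, and centring kept 226, ended 9 and made 2. The variance settings, the brightness filters and averaging probesets each kept at least 213 and ended at most 8.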

Other observations

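Of the tests in this part, the splits of the arrays and the test of genes near Esr1 were chosen before their results were seen, while the settings with 14 and 12 arrays were chosen after.

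Over the 14 arrays, without both 18-hour replicates 2, untreated knockout extracts differed from wild type in several genes outside the fixed lists. Higher were the galactosyltransferase Ugt8a (4.71 ± 0.50, adjusted p = 0.00967) and the chondroitin sulfotransferase Chst11 (4.25 ± 0.52, adjusted p = 0.021). Also higher were the ferritin receptor Timd2 (4.23 ± 0.35, adjusted p = 0.00442), the N-acetyltransferase Nat2 (2.05 ± 0.30, adjusted p = 0.0476) and the laminin chain Lama3 (1.20 ± 0.17, adjusted p = 0.0453). Igfals, which holds insulin-like growth factors in the circulation, was lower (-3.34 ± 0.44, adjusted p = 0.0269). At 2 weeks the bile acid receptor Nr1h4 was higher in knockout (2.76 ± 0.28, adjusted p = 0.026). Irf1 (-1.11 ± 0.14, adjusted p = 0.0491) and the leukocyte phosphatase Ptprc (-1.17 ± 0.14, adjusted p = 0.0453) were lower. Of these 3, Irf1 was also called over 16 arrays (adjusted p = 0.0231), and Nr1h4 (0.101) and Ptprc (0.0501) were not. Without knockout 2 weeks replicate 1, over the 13 arrays, none was called: Nr1h4 was at 2.55 (adjusted p = 0.0755), Irf1 at -0.947 and Ptprc at -1.05 (adjusted p = 0.138 for both), with 1 knockout array left at 2 weeks.

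Whether random grouping could give the genotype counts was tested with other splits of the arrays within each time. Over all 16 arrays the labels gave 0 genes, so all 100 of the 100 splits fitted gave as many by necessity, and chance is not excluded. The highest of the others gave 1583, which points to a structure of the samples that the labels do not follow. It is the count that exchanging the 18-hour replicate 2 labels also gave, so it is no further support for that pattern. Over the 12 arrays without any 18-hour array, the labels gave 449 genes, the highest of the other splits gave 98, and 1 of 100 splits (the labels themselves) gave as many. Random grouping is thus argued against within these 12 arrays as given. The set was formed after the 18-hour arrays were seen, a choice the splits do not repeat.

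A chromosome segment of another strain, carried along with the knockout allele, could place differing genes next to Esr1. Of the 50 measured genes nearest to Esr1 on chromosome 10, 1 was called over the 12 arrays, Ccdc170 (-0.50), where 0.745 were expected by chance (one-sided Fisher's exact p = 0.528). Called genes were thus not over-represented among these 50. Because 50 genes could hold only a small part of the 449 calls, the test does not bear on the source of the others. Ccdc170 lies 2 measured genes from Esr1, so an effect of such a segment on it is not excluded. Segments elsewhere, and effects of a segment on distant genes, were not tested.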
